A study of Rattus norvegicus with 20 samples.

How the data were processed

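Rat globular bushy cells were labelled by cholera toxin B taken up in the contralateral medial nucleus of the trapezoid body, per the labels' protocols. Sections of 12 µm were made 24 hours after the injection, 200 labelled cells per animal were isolated by laser microdissection, and their RNA went through 2 rounds of linear amplification with biotin labelling in the later round. The labels number 6 biological replicates at P3, 9 at P8 and 5 at P21. The deposited table holds 1 linear intensity per probe set and array, from 0 upwards with 1 decimal. The submitters' processing notes name GCRMA with no version and no role. GCRMA gives log2 values, whereas the deposited intensities are linear, and the tool that made them is not given in the sources used here. On every array the mean intensity over the probe sets without the lowest and highest 2% was 100 to 3 digits, so each array was scaled as a whole, with no further normalization added here. All 20 columns of the table matched a sample by name.

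The table has 31099 probe sets, of which 57 are controls. By the platform annotation 20832 probe sets have 1 gene, 436 have several and 9831 are unnamed here, and only those with 1 gene were used. Symbols were updated through a rat RefSeq gene table of assembly GRCr8, used for names alone: 20764 through the Entrez identifier, 2 through the accession, and 66 kept as annotated. This gave 14218 genes. A gene was represented by its probe set with the highest mean. Probe sets above log2 4 in at least 5 arrays were tested, 12705 genes over 20 arrays and 11830 over 15.

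Values were analysed as log2(intensity + 1), so the pseudocount of 1 understates changes of dim genes. Group means, differences and standard errors came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 3 ages in 1 fit), and adjusted p from Benjamini-Hochberg over the genes tested, with calls under 0.05. Every adjusted p of a gene in the text is from limma. Gene lists were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives, for lists with at least 5 tested genes. There were 36 lists, written before the data were examined: 11 of markers of other cell types and the others of neuronal, synaptic and metabolic functions. Of their 1143 entries 984 matched a measured gene, by a rule for matching older names that was corrected after the first look at the data. Array measures were compared by exact permutation tests over all regroupings, counting differences of either sign. Both intervals share P8, so unchanged groups of the same sizes were simulated 20 times. The number of arrays limits the precision, and the labels call the samples biological replicates without naming litters or dates.

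Genes are named by a rule fixed with the lists. It takes, for each contrast, the 6 largest rises and the 6 largest falls among called genes whose groups do not overlap and whose higher group averages at least log2 6. It adds up to 4 genes with the smallest p from each list and contrast, and 35 genes always named if measured, of which 28 were tested. A gene singled out beside a list because it went against the others was chosen after its values were seen.

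Alternatives were other filters, quantile normalization, subtraction of array medians, a floor, other variance models, array weights, other treatments of several probe sets per gene, a 2-fold threshold, the replicate number as a block, covariates for oligodendrocyte content and for the 3' minus 5' difference, an exact Mann-Whitney test, only the ages compared, and each array left out. Leaving out P8 replicates 5 to 9 and a pseudocount of 16 were chosen after seeing the data. Subtracting medians removes a shift of the median over tested genes of 0.12 from P3 to P8, -0.12 from P8 to P21 and -0.0064 from P3 to P21 over 20 arrays. Over 15 arrays these shifts are -0.015, 0.004 and -0.011.

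The tests were tried on simulated data with 50 genes changed at each of 1.5, 2, 4 and 8-fold. Over 20 arrays limma called 0, 7, 41 and 49 of them for P8 vs P3, 0, 7, 31 and 46 for P21 vs P8 and 0, 4, 35 and 45 for P21 vs P3. Over 15 arrays it called 11, 27, 44 and 50, 2, 22, 45 and 49 and 9, 30, 45 and 50. Unchanged genes called were 4, 2 and 10 over 20 arrays and 5, 13 and 5 over 15. The exact Mann-Whitney test called 0. Except for P8 vs P3 over 20 arrays this was fixed beforehand. With so few changed genes its smallest possible p cannot pass the adjustment. A list shifted on purpose was always called and 0 others were. Genes correlated as in the data (to 0.59) were not simulated.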

Results

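Globular bushy cells of the rat ventral cochlear nucleus send their axons to the contralateral medial nucleus of the trapezoid body, where each axon forms a giant terminal, the calyx of Held. Their gene expression was profiled at 3 postnatal ages: P3, when the calyx has just formed, P8, a juvenile stage, and P21, when the synapse is mature. A fluorescent tracer injected on the target side marked the cells, and 200 per animal were cut out by laser microdissection. The series holds 20 arrays of separate animals: 6 at P3, 9 at P8 and 5 at P21. Levels below are log2(intensity + 1), and changes are differences of group means on that scale with their standard errors. The question is which genes change from synapse formation to the mature synapse.

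The arrays of P8 replicates 5 to 9 stood apart from the other 15 in their control probe sets. Their spike-in controls, bacterial transcripts added to every sample, averaged 13.22 ± 0.37 (SD, n = 5) against 8.85 ± 0.35 (SD, n = 4) in P8 replicates 1 to 4. Against all other arrays the rise was 4.39 on the log2 scale, with no p given as these controls defined the sets. Their median intensities were 58.9 to 67.5, against 23.8 to 32.5 on the other arrays, and 77.1 to 80.5% of their probe sets lay above log2 4, against 59.5 to 67.6%. The mean correlation across probe sets was 0.948 within P3, 0.925 within P21, 0.895 among P8 replicates 1 to 4 and 0.704 among P8 replicates 5 to 9, but 0.531 between these sets of P8 arrays. P8 replicates 1 to 4 correlated at 0.888 with the P3 arrays and at 0.872 with the P21 arrays. Each comparison is therefore given over all 20 arrays, the design chosen before the data were examined, and over the 15 arrays without P8 replicates 5 to 9, chosen after the controls had been seen.

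**Figure D1:**
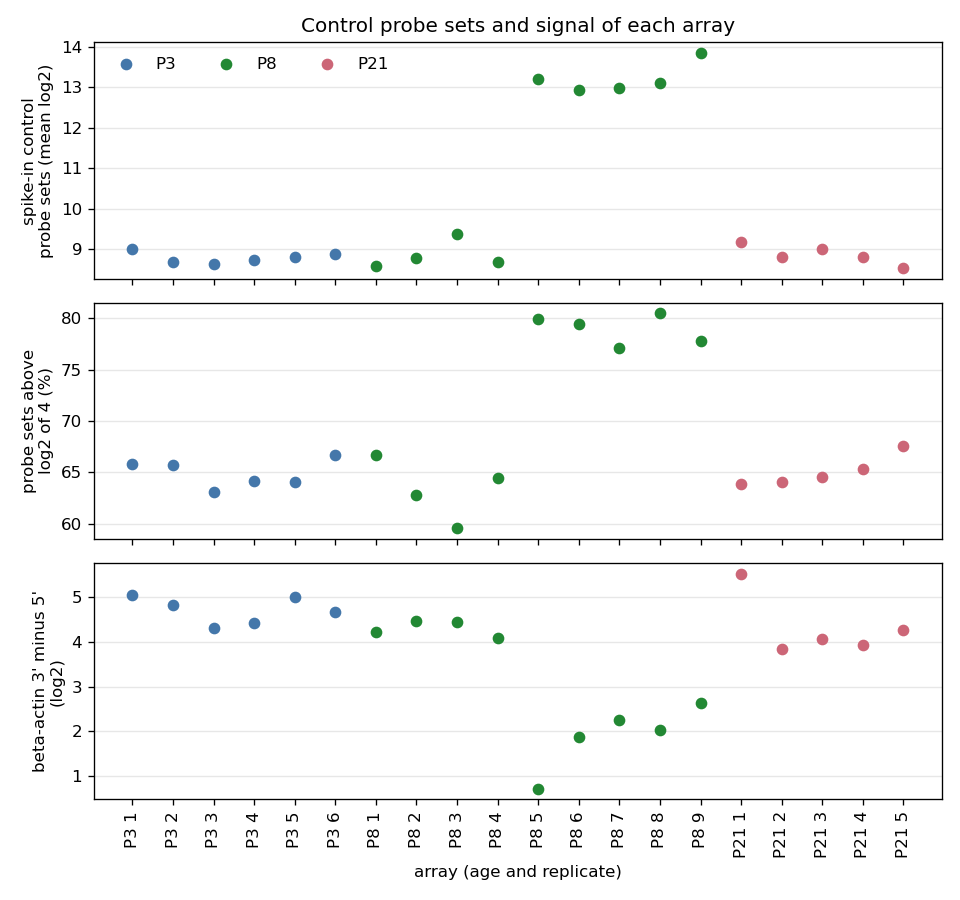
Mean log2 signal of the spike-in control probe sets (top), percent of probe sets above log2 4 (middle) and the 3' minus 5' log2 difference of the beta-actin controls (bottom) for each of the 20 arrays, coloured by age. P8 replicates 5 to 9 lie at 12.94 to 13.85 in the top panel, where the other arrays lie at 8.53 to 9.36.

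A control of RNA length and markers of other cell types also moved with age. The 3' minus 5' difference of the GAPDH controls, which grows as amplified RNA gets shorter, was 2.91 ± 0.27 (SD, n = 6) at P3 and 3.99 ± 0.66 (SD, n = 5) at P21 (exact permutation p = 0.00216, 0.0292 after adjustment over 108 two-sided tests of array measures). For beta-actin it was 4.29 ± 0.19 in P8 replicates 1 to 4 (SD, n = 4) and 1.90 ± 0.72 in P8 replicates 5 to 9 (SD, n = 5; exact permutation p = 0.00794, 0.0296 after adjustment). The mean of the oligodendrocyte and myelin markers went from 5.65 ± 0.37 at P3 (SD, n = 6) to 7.74 ± 0.24 at P21 (SD, n = 5; exact permutation p = 0.00216, 0.0292 after adjustment). From P3 to P21 the means of oligodendrocyte precursors, inhibitory neurons and Schwann cells changed by -0.67, -0.62 and 0.55. Their exact permutation p was 0.0292, 0.0312 and 0.0296 after adjustment. From P3 to P8 replicates 1 to 4 the oligodendrocyte mean rose by 1.54 (exact permutation p = 0.00476, 0.0296 after adjustment), while the means of cerebellar granule cells and of microglia differed by -0.69 and -0.60 (exact permutation p = 0.0296 and 0.0571 after adjustment). Between the sets of P8 arrays, microglial markers were higher by 1.56 and choroid plexus markers by 1.12 in replicates 5 to 9, and astrocyte markers differed by -0.63 (exact permutation p = 0.0296 after adjustment for each). Those of granule cells, inhibitory neurons, fibroblasts and oligodendrocytes differed by 0.86, 0.71, 0.35 and -0.40 (exact permutation p = 0.0490 after adjustment for each). Beside random lists 0 of 11 marker lists passed the upper bound (percentiles 94.26 for microglia, 72 for choroid plexus).

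Between P3 and P21 several genes of fast auditory neurons rose and several genes of axon growth fell. Scn4b, the sodium channel beta4 subunit of fast-firing neurons, rose by 5.26 ± 0.46 on the log2 scale (adjusted p = 3.23e-07), from 6.20 at P3 to 11.46 at P21. Kcnc1 and Kcna1, which encode potassium channel subunits for rapid repolarisation and low-threshold conductance, rose by 3.27 ± 0.32 and 4.34 ± 0.84 (adjusted p = 1.08e-06 and 0.00104). The calcium buffers Pvalb and Calb2 rose by 6.28 ± 0.91 and 2.95 ± 0.57 (adjusted p = 5.63e-05 and 0.00100). The growth cone protein gene Gap43 fell by 2.76 ± 0.34 (adjusted p = 1.04e-05), and Dcx, for a microtubule protein of immature neurons, fell by 4.57 ± 0.62 (adjusted p = 3.11e-05). The myelin gene Mbp rose by 3.17 ± 0.66 (adjusted p = 0.00193). In each of these genes all 5 P21 arrays lay on the same side of all 6 P3 arrays.

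Among genes whose ages did not overlap, the 6 with the largest rises were Ermn and Opalin of oligodendrocytes, Pvalb, the D-amino acid oxidase Dao, the cytochrome oxidase subunit Cox8b and the growth factor Fgf1. Ermn rose by 6.58 ± 0.83, Dao by 6.03 ± 0.50 and Cox8b by 5.79 ± 0.76. Opalin and Fgf1 rose by 5.30 ± 0.60 and 5.26 ± 0.69, and adjusted p of the 6 ran from 2.21e-07 for Dao to 5.63e-05 for Pvalb. The largest falls were -6.47 ± 0.66 for the homeobox factor Gbx2 and -5.79 ± 0.67 for Scn3a, a sodium channel of the developing brain. The myosin heavy chain Myh6 changed by -4.57 ± 0.87 and the ubiquitin ligase Marchf1 by -4.48 ± 0.85. Glra2, the glycine receptor subunit of immature neurons, changed by -4.57 ± 1.28 (adjusted p = 0.0177). The Glra2 call ended in 2 of 20 leave-one-out fits (adjusted p = 0.0617 without P21 replicate 3) and passed over the 15 arrays (adjusted p = 1.93e-04). The plot of single genes shows each array.

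**Figure D2:**
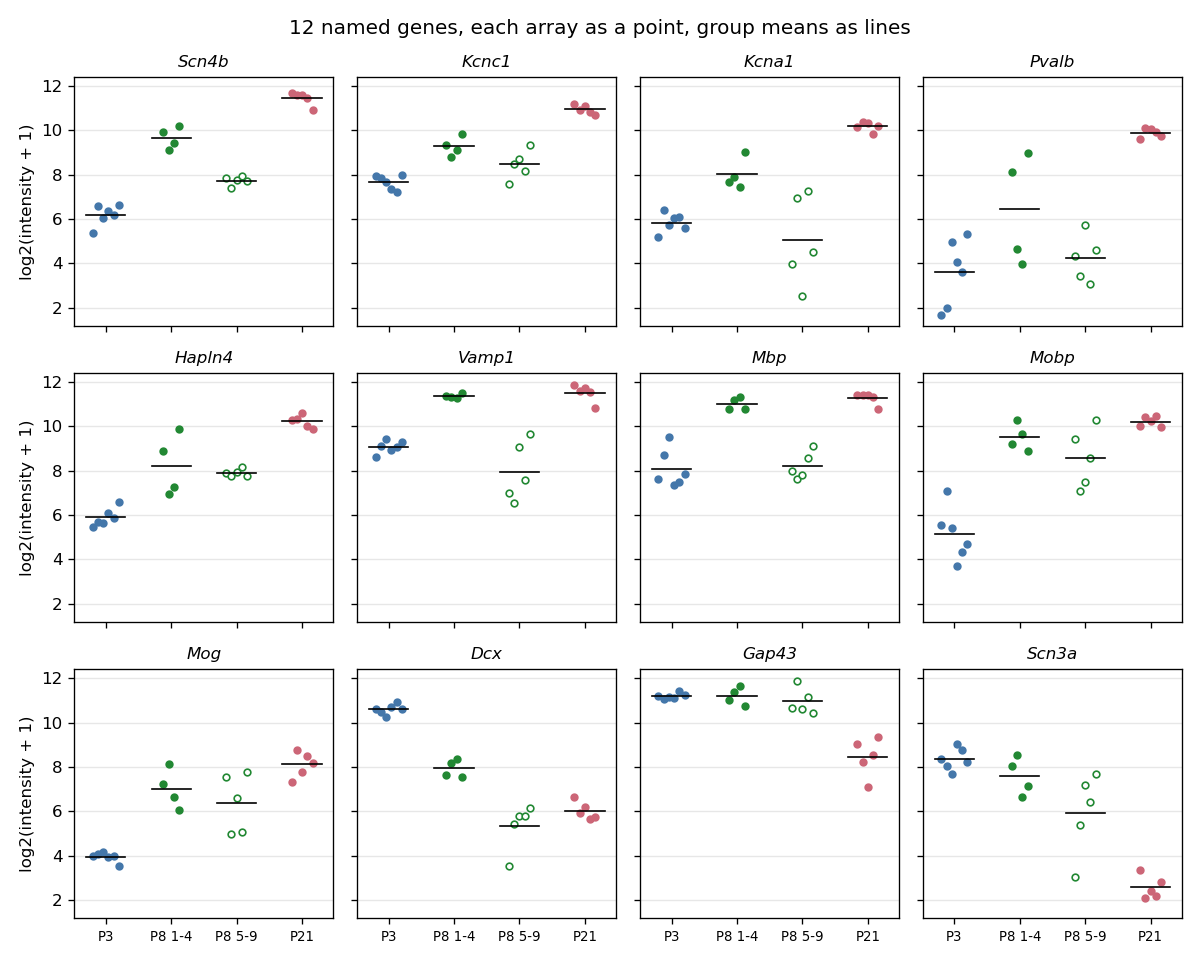
Log2(intensity + 1) of 12 named genes on each array, with P3, P8 replicates 1 to 4, P8 replicates 5 to 9 (open circles) and P21 side by side and lines at the means. Scn4b goes from a mean of 6.20 at P3 to 9.68 in P8 replicates 1 to 4, 7.72 in P8 replicates 5 to 9 and 11.46 at P21.

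Of the 36 gene lists, 8 differed between P3 and P21 over the 20 arrays by camera with its preset correlation, 4 upwards and 4 downwards. With an estimated correlation 5 of these held: bushy cell, oligodendrocyte, axon growth, guidance and cell cycle genes. Of 24 genes of bushy cells and fast auditory neurons, 15 rose, 0 fell and 9 did not pass, or 18 and 0 adjusted over the list alone. The median was 1.53 (adjusted p = 4.49e-12). Besides Scn4b and Kcnc1, Hapln4, a link protein of perineuronal nets, rose by 4.34 ± 0.39 and the potassium channel subunit Kcna2 by 2.62 ± 0.34 (adjusted p = 4.44e-07 and 1.68e-05). Of 28 oligodendrocyte and myelin genes, markers of another cell type, 20 rose, 1 fell and 7 did not pass, or 24 and 2 adjusted over the list alone. The median was 2.07 (adjusted p = 7.03e-15). Mobp, Mog and Mal rose by 5.09 ± 0.57, 4.16 ± 0.48 and 4.01 ± 0.47 (adjusted p = 3.91e-06, 5.09e-06 and 5.44e-06). Of 32 axon growth and neuronal immaturity genes, 1 rose, 15 fell and 16 did not pass, or 1 and 20 adjusted over the list alone. The median was -1.32 (adjusted p = 4.76e-11). Dpysl5, Marcks and Sox4, of growth cones and neuronal differentiation, changed by -3.79 ± 0.41, -2.46 ± 0.27 and -2.66 ± 0.33 (adjusted p = 2.60e-06, 3.57e-06 and 1.04e-05). The 1 member that rose was Cd24, a surface glycoprotein, by 1.35 ± 0.40 (adjusted p = 0.0234), a call that ended in 3 leave-one-out fits (adjusted p = 0.0682 without P21 replicate 3).

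Of 41 axon guidance ligands and receptors, 2 rose, 13 fell and 26 did not pass, or 2 and 14 adjusted over the list alone. The median was -0.23 (adjusted p = 0.00245). The ligands Efnb3 and Rgma changed by -4.09 ± 0.42 and -1.83 ± 0.26, while the semaphorin receptor Nrp2 rose by 1.72 ± 0.31 (adjusted p = 1.54e-06, 4.07e-05 and 5.34e-04). Of 33 cell cycle genes, 1 rose, 13 fell and 19 did not pass, or 1 and 20 adjusted over the list alone. The median was -1.25 (adjusted p = 1.32e-08). The mitotic genes Kif20a, Top2a and Ccnb2 changed by -2.61 ± 0.41, -3.01 ± 0.53 and -2.63 ± 0.49 (adjusted p = 1.58e-04, 4.61e-04 and 8.50e-04). The 1 member that rose was the G1 cyclin Ccnd1, by 2.08 ± 0.36 (adjusted p = 3.46e-04). Over the same ages the marker mean of oligodendrocyte precursors, which are dividing cells, fell by 0.67. Of 42 ribosomal protein genes, 0 rose, 12 fell and 30 did not pass, or 0 and 15 adjusted over the list alone. The median was -0.82 (adjusted p = 3.61e-08, and adjusted p = 0.179 with an estimated correlation). Rpl35 and Rpl22 changed by -1.41 ± 0.26 and -1.31 ± 0.27 (adjusted p = 8.30e-04 and 0.00161).

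Lists of energy and sterol metabolism were called upwards. Of 68 oxidative phosphorylation genes, 8 rose, 0 fell and 60 did not pass, or 8 and 0 adjusted over the list alone. The median was 0.43 (adjusted p = 4.52e-05, and adjusted p = 0.584 with an estimated correlation). Ndufs4 and Ndufb7 of respiratory complex I rose by 2.25 ± 0.31 and 1.62 ± 0.26 (adjusted p = 3.51e-05 and 1.41e-04). Of 20 cholesterol synthesis genes, 5 rose, 0 fell and 15 did not pass, or 5 and 0 adjusted over the list alone. The median was 0.53 (adjusted p = 0.0173, and adjusted p = 0.478 with an estimated correlation). The sterol carrier Stard4 rose by 1.99 ± 0.34 and the squalene synthase Fdft1 by 1.18 ± 0.28 (adjusted p = 3.72e-04 and 0.00605). With the oligodendrocyte mean as covariate the list means of oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis turned to -0.91, -2.08 and -1.51 over 20 arrays, called downwards (adjusted p = 0.0434, 0.00184 and 0.0164), and those of cholesterol synthesis and the axonal cytoskeleton turned to -0.94 and -0.31 without being called. Over the 15 arrays these 8 lists were called in the same direction and 3 more were added, but with an estimated correlation only the cell cycle list held there (adjusted p = 0.0480). The lists of bushy cell, oligodendrocyte, axon growth and guidance genes then had adjusted p = 0.117, 0.138, 0.0719 and 0.172. In the tricarboxylic acid cycle 10 of 19 rose and 1 fell, or 10 and 1 adjusted over the list alone. The median was 0.39 (adjusted p = 0.0136, and adjusted p = 0.476 with an estimated correlation). In glycolysis 12 of 27 rose and 2 fell, or 13 and 2 adjusted over the list alone. The median was 0.43 (adjusted p = 0.0321, and adjusted p = 0.442 with an estimated correlation). The phosphofructokinase Pfkm rose by 1.45 ± 0.17 and the lactate dehydrogenase Ldha fell by 1.99 ± 0.18 (adjusted p = 8.69e-06 and 9.29e-07). In neurofilaments and the axonal cytoskeleton 14 of 29 rose and 4 fell, or 15 and 5 adjusted over the list alone. The median was 0.45 (adjusted p = 0.0453, and adjusted p = 0.412 with an estimated correlation). The microtubule protein Map1a rose by 1.70 ± 0.20 and the adducin Add2 fell by 3.35 ± 0.41 (adjusted p = 9.32e-06 and 1.31e-05). The glycolysis call ended in 1 leave-one-out fit (adjusted p = 0.0554 without P21 replicate 2) and the cytoskeleton call in 8 (adjusted p = 0.0770 without P21 replicate 1).

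**Figure D3:**
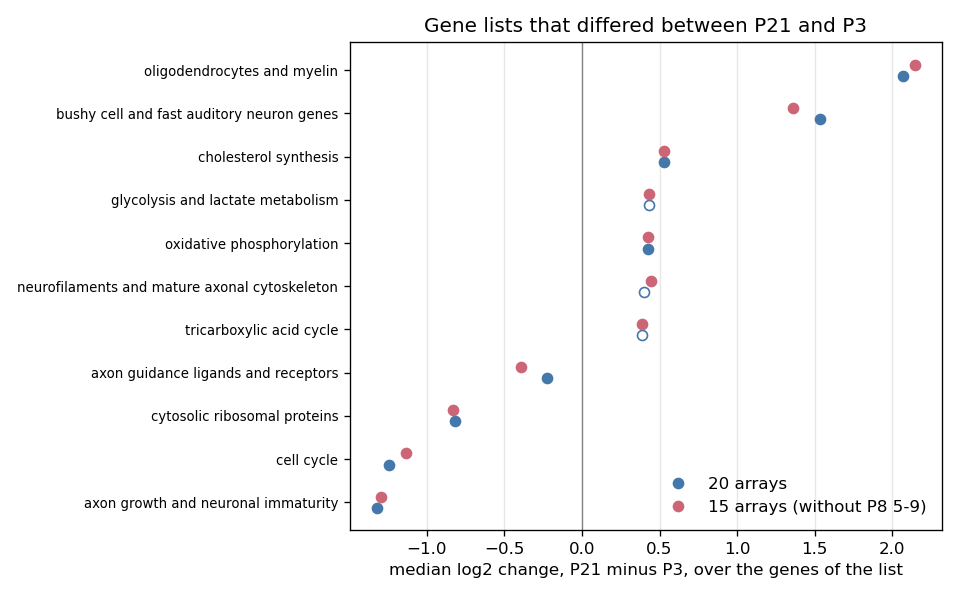
Median log2 change from P3 to P21 over the genes of each list called by camera in either set of arrays, over 20 arrays (blue) and 15 arrays (red), with open circles for lists not called in that set. Oligodendrocyte and myelin genes have the highest median, 2.07 over 20 arrays, and axon growth genes the lowest, -1.32.

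Of 45 synaptic vesicle genes, 4 rose, 5 fell and 36 did not pass over 20 arrays (6 and 5 adjusted over the list alone; adjusted p = 0.218). Over 15 arrays 16 of 42 rose and 7 fell (adjusted p = 0.0733). Single genes follow. Vamp1, the vesicle SNARE of fast synapses, rose by 2.44 ± 0.79 (adjusted p = 0.0410). That call ended in 11 of 20 leave-one-out fits (adjusted p = 0.0864 without P21 replicate 1) and had adjusted p = 1.71e-07 over the 15 arrays. The neurofilament gene Nefh rose by 1.36 ± 0.45 (adjusted p = 0.0459), a call that ended in 10 of these fits (adjusted p = 0.0991 without P21 replicate 1). Cacna1b, an N-type calcium channel subunit, fell by 1.03 ± 0.29 (adjusted p = 0.0175), with adjusted p = 0.0592 without P21 replicate 3. The vesicular glutamate transporters Slc17a6 and Slc17a7 stood at 0.15 ± 0.39 and 1.28 ± 0.48 (adjusted p = 0.881 and 0.0799). The calcium sensors of release Syt1 and Syt2 stood at 0.27 ± 0.34 and 1.28 ± 0.49 (adjusted p = 0.697 and 0.0830). The SNARE genes Snap25 and Vamp2 stood at 0.40 ± 0.32 and -0.97 ± 0.52 (adjusted p = 0.471 and 0.241), and the complexins Cplx1 and Cplx2 at 0.63 ± 0.39 and -0.76 ± 0.56 (adjusted p = 0.332 and 0.436). For the active zone genes Bsn, Pclo, Rims1 and Unc13b the changes were -0.08, 0.42, 0.40 and -0.96, and for the vesicle protein gene Tprg1l 0.12 (lowest adjusted p = 0.560, for Unc13b). The chloride extruder Slc12a5, the P/Q-type calcium channel gene Cacna1a and Nefm stood at 0.97 ± 0.35, 0.17 ± 0.55 and 0.27 ± 0.42 (adjusted p = 0.0643, 0.908 and 0.765). Gfap of astrocytes and Gad1 of inhibitory neurons stood at 0.56 ± 0.46 and -0.99 ± 0.44 (adjusted p = 0.499 and 0.147).

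More of these genes passed over the 15 arrays. The change from P3 to P21 is the same in both sets, but its standard error also draws on the P8 arrays, and for Snap25 it was 0.32 over 20 arrays and 0.14 over 15. Slc17a7, Syt2, Snap25, Cplx1 and Slc12a5 were called higher at P21 over 15 arrays (adjusted p = 0.0413, 0.0298, 0.0355, 0.00459 and 2.25e-04) and Vamp2 and Gad1 lower (7.02e-04 and 0.00789). Another probe set of Vamp2 had the opposite sign. The calls of Slc17a7, Snap25 and Syt2 ended in 10, 8 and 5 of 15 leave-one-out fits (adjusted p = 0.0826 and 0.0892 without P21 replicate 3 and 0.0653 without P3 replicate 2). In all, 935 genes were higher and 996 lower at P21 than at P3 over 20 arrays, of 12705 tested. Over 15 arrays 2664 were higher and 2410 lower, of 11830 tested, and 1913 genes were called in both sets. The 20-array balance turned with a filter at log2 6 (956 and 930), array weights (2930 and 2864), only these ages (3008 and 2724) and the exact Mann-Whitney test (2725 and 2421), and that over 15 with a 2-fold threshold (1124 and 1290). The GAPDH 3' minus 5' difference was 1.08 higher at P21. With each array's oligodendrocyte mean, which follows age, as a covariate the counts became 4 over 20 arrays and 18 over 15.

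From P3 to P8 the fast-neuron genes Scn4b and Hapln4 and the myelin genes Mobp and Mog rose, and Dcx and Cd24 of immature neurons fell, in both sets of arrays. Scn4b rose by 2.39 ± 0.40 over 20 arrays and 3.48 ± 0.26 over 15 (adjusted p = 0.00113 and 9.97e-06), and Hapln4 by 2.16 ± 0.34 and 2.34 ± 0.45 (adjusted p = 8.23e-04 and 0.00295). The myelin gene Mobp rose by 3.86 ± 0.50 over 20 arrays and 4.37 ± 0.49 over 15 (adjusted p = 1.38e-04 and 8.04e-05), and Mog by 2.71 ± 0.42 and 3.06 ± 0.34 (adjusted p = 7.70e-04 and 8.76e-05). Dcx changed by -4.11 ± 0.54 and -2.66 ± 0.22 (adjusted p = 1.50e-04 and 1.03e-05), and Cd24 by -2.66 ± 0.35 and -2.75 ± 0.36 (adjusted p = 1.38e-04 and 2.27e-04).

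Further genes with large rises were C1qtnf12, a relative of adiponectin, the lipase Pnlip and the collagen Col9a3. They rose by 2.60 ± 0.48, 2.57 ± 0.28 and 2.52 ± 0.42 over 20 arrays and by 1.20 ± 0.21, 2.09 ± 0.29 and 1.54 ± 0.37 over 15 (adjusted p = 0.00198, 3.22e-04 and 0.0105 over 15). Over 15 arrays the serotonin receptor gene Htr2c rose by 6.18 ± 0.72 and Enpp6, of newly formed oligodendrocytes, by 3.52 ± 0.70 (adjusted p = 1.00e-04 and 0.00381). The calcium buffer Calb1 and Cntnap1, a protein of the axonal paranode, rose by 3.59 ± 0.60 and 3.41 ± 0.28 (adjusted p = 0.00140 and 1.03e-05). Over 20 arrays their calls ended in 15 and 6 leave-one-out fits (adjusted p = 0.0913 without P3 replicate 5 and 0.0636 without P3 replicate 1). The calponin Cnn3, the tumour necrosis factor receptor Tnfrsf1a and the ribosomal stalk protein Rplp0 changed by -3.84 ± 0.73, -3.34 ± 0.56 and -3.30 ± 0.88 over 20 arrays, and by -1.64 ± 0.29, -2.83 ± 0.59 and -0.85 ± 0.21 over 15 (highest adjusted p = 0.0161, for Rplp0 over 20 arrays). The glutathione peroxidase Gpx1 changed by -3.17 ± 0.86 and -0.90 ± 0.18 (adjusted p = 0.0170 and 0.00416). The transcription factor Myc fell by 3.06 ± 0.72 over 20 arrays (adjusted p = 0.00877) and stood at -1.26 ± 0.56 over 15 (adjusted p = 0.137). Over 15 arrays the lipase inhibitor Angptl4, the lipopolysaccharide co-receptor Cd14 and the G protein regulator Rgs16 changed by -2.98 ± 0.62, -2.80 ± 0.65 and -2.68 ± 0.61 (adjusted p = 0.00481, 0.00975 and 0.00834). The exonuclease Eri2 changed by -2.96 ± 0.85 (adjusted p = 0.0260), a call that ended in 3 leave-one-out fits (adjusted p = 0.0815 without P8 replicate 2). Over 20 arrays the Cd14 call ended in 1 (adjusted p = 0.0548 without P3 replicate 5).

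Of the 36 lists, 8 were called over 20 arrays and 13 over 15, and with an estimated correlation 0 and 1 of these held. Over 20 arrays camera with the estimated correlation gave 4 lists at an unadjusted p under 0.05, and fry called 10 lists. Of 28 oligodendrocyte and myelin genes, 17 rose, 2 fell and 9 did not pass over 20 arrays, or 20 and 2 adjusted over the list alone. The median was 1.33 (adjusted p = 7.28e-07, and adjusted p = 0.106 with an estimated correlation). Over 15 arrays 17 of 27 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 1.17 and adjusted p = 1.93e-10, and adjusted p = 0.0954 with an estimated correlation. Mag and Opalin rose by 1.97 ± 0.26 and 3.42 ± 0.52 over 20 arrays (adjusted p = 1.50e-04 and 6.89e-04). Mbp stood at 1.36 ± 0.57 over 20 arrays and rose by 2.92 ± 0.35 over 15 (adjusted p = 0.0745 and 1.38e-04). Of 24 bushy cell genes, 9 rose, 0 fell and 15 did not pass over 20 arrays, or 9 and 0 adjusted over the list alone. The median was 0.62 (adjusted p = 0.0356, and adjusted p = 0.687 with an estimated correlation). Over 15 arrays 12 of 23 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.11 and adjusted p = 6.91e-08, and adjusted p = 0.0954 with an estimated correlation. Kcna2 and Kcnc1 rose by 1.33 ± 0.30 and 1.15 ± 0.28 over 20 arrays (adjusted p = 0.00646 and 0.0104). Kcna1 stood at 0.52 ± 0.73 over 20 arrays and rose by 2.17 ± 0.28 over 15 (adjusted p = 0.597 and 2.28e-04). Of 34 potassium and HCN channel genes, 9 rose, 2 fell and 23 did not pass over 20 arrays, or 9 and 2 adjusted over the list alone. The median was 0.51 (adjusted p = 0.0302, and adjusted p = 0.106 with an estimated correlation). Over 15 arrays 10 of 33 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.41 and adjusted p = 0.00114. The 20-array call of the bushy cell list ended in 4 leave-one-out fits (adjusted p = 0.133 without P8 replicate 4) and that of the potassium channels in 1 (adjusted p = 0.0660 without P8 replicate 3).

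Axon growth and ribosomal genes were called downwards in both sets. Of 32 axon growth genes, 2 rose, 18 fell and 12 did not pass over 20 arrays, or 2 and 18 adjusted over the list alone. The median was -0.75 (adjusted p = 1.11e-04, and adjusted p = 0.106 with an estimated correlation). Over 15 arrays 0 of 31 rose and 7 fell (0 and 9 adjusted over the list alone), with a median of -0.27 and adjusted p = 5.42e-04, and adjusted p = 0.218 with an estimated correlation. Sox4 and Dpysl5 changed by -1.75 ± 0.29 and -1.92 ± 0.36 over 20 arrays (adjusted p = 9.73e-04 and 0.00236). Of 42 ribosomal protein genes, 2 rose, 22 fell and 18 did not pass over 20 arrays, or 3 and 28 adjusted over the list alone. The median was -0.76 (adjusted p = 7.28e-07, and adjusted p = 0.422 with an estimated correlation). Over 15 arrays 0 of 41 rose and 9 fell (0 and 11 adjusted over the list alone), with a median of -0.31 and adjusted p = 9.96e-06, and adjusted p = 0.396 with an estimated correlation. Rps15a and Rpl24 changed by -1.30 ± 0.26 and -1.60 ± 0.31 over 20 arrays (adjusted p = 0.00336 and 0.00291). Markers of choroid plexus and ependyma were called upwards over 20 arrays. Of 12 such markers, 4 rose, 0 fell and 8 did not pass, or 4 and 0 adjusted over the list alone. The median was 0.74 (adjusted p = 0.0302, and adjusted p = 0.687 with an estimated correlation). Over 15 arrays they were not called (adjusted p = 0.582), and their mean was 1.12 higher in P8 replicates 5 to 9 than in replicates 1 to 4.

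The oxidative phosphorylation list was called downwards over 20 arrays and upwards over 15. Of 68 genes of this list, 8 rose, 5 fell and 55 did not pass over 20 arrays, or 4 and 0 adjusted over the list alone. The median was -0.48 (adjusted p = 0.0302, and adjusted p = 0.920 with an estimated correlation). Over 15 arrays 9 of 68 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.22 and adjusted p = 1.11e-04, and adjusted p = 0.718 with an estimated correlation. The tricarboxylic acid cycle was likewise called downwards over 20 arrays and upwards over 15. Of 19 genes of the cycle, 0 rose, 3 fell and 16 did not pass over 20 arrays, or 0 and 2 adjusted over the list alone. The median was -0.92 (adjusted p = 0.00287, and adjusted p = 0.693 with an estimated correlation). Over 15 arrays 4 of 19 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.20 and adjusted p = 0.0484, and adjusted p = 0.718 with an estimated correlation. Dlst, a subunit of the oxoglutarate dehydrogenase complex, stood at -1.46 ± 0.76 over 20 arrays and rose by 0.87 ± 0.16 over 15 (adjusted p = 0.140 and 0.00269). Ndufs4 rose by 0.94 ± 0.27 and 1.40 ± 0.20 (adjusted p = 0.0205 and 4.33e-04; over 20 arrays adjusted p = 0.0507 without P3 replicate 5). The oxidative phosphorylation call over 20 arrays ended in 5 leave-one-out fits (adjusted p = 0.117 without P8 replicate 8) and the cycle's call over 15 in 8 (adjusted p = 0.196 without P8 replicate 4).

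Over 15 arrays 6 further lists were called. Upwards, of synaptic vesicle genes 12 of 42 rose and 1 fell, or 14 and 1 adjusted over the list alone. The median was 0.36 (adjusted p = 1.13e-04, and 0.131 with an estimated correlation), but -0.023 over 20 arrays. The synapsin Syn2 rose by 1.21 ± 0.18 (adjusted p = 7.50e-04). Of calcium buffers, pumps and exchangers, upwards, 8 of 28 rose and 0 fell, or 8 and 0 adjusted over the list alone. The median was 0.34 (adjusted p = 9.03e-04, and 0.0954 with an estimated correlation). The exchanger Slc24a2 and Calb2 rose by 1.66 ± 0.18 and 1.59 ± 0.28 (adjusted p = 6.53e-05 and 0.00197). Of endocytosis genes, upwards, 5 of 35 rose and 2 fell, or 7 and 2 adjusted over the list alone. The median was 0.20 (adjusted p = 0.0376, and 0.131 with an estimated correlation), but -0.12 over 20 arrays. That call ended in 4 leave-one-out fits (adjusted p = 0.0790 without P8 replicate 4). Downwards, of cell cycle genes 0 of 32 rose and 8 fell, or 0 and 8 adjusted over the list alone. The median was -0.58 (adjusted p = 5.09e-05, and 0.0954 with an estimated correlation). The replication factor Mcm7 changed by -1.16 ± 0.16 (adjusted p = 4.28e-04). Of microglial markers, downwards, 0 of 17 rose and 3 fell, or 0 and 5 adjusted over the list alone. The median was -0.69 (adjusted p = 0.00625, and 0.312 with an estimated correlation), but 0.42 over 20 arrays. The protease Ctss of microglia changed by -1.33 ± 0.38 (adjusted p = 0.0253), a call that ended in 5 leave-one-out fits (adjusted p = 0.0700 without P8 replicate 3). Of cerebellar granule cell markers, downwards, 1 of 12 rose and 4 fell, or 1 and 6 adjusted over the list alone. The median was -0.82 (adjusted p = 0.0376, and 0.396 with an estimated correlation). That call ended in 1 leave-one-out fit (adjusted p = 0.0790 without P8 replicate 4).

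Among genes of release and inhibition, Vamp1 stood at 0.40 ± 0.69 over 20 arrays and rose by 2.30 ± 0.20 over 15 (adjusted p = 0.672 and 1.22e-05). Slc12a5 stood at 0.11 ± 0.30 and rose by 0.87 ± 0.17 (adjusted p = 0.804 and 0.00374). Syt2 and Snap25 rose by 1.54 ± 0.42 and 0.85 ± 0.27 over 20 arrays (adjusted p = 0.0176 and 0.0313) and stood at 1.11 ± 0.47 and 0.33 ± 0.15 over 15 (adjusted p = 0.120 and 0.152). The Snap25 call ended in 7 leave-one-out fits (adjusted p = 0.0592 without P3 replicate 4). In all, 2022 genes were higher and 1495 lower at P8 than at P3 over 20 arrays, and 1098 and 948 over 15. The balance over 20 arrays turned with array medians subtracted (1740 and 1765), a filter at log2 6 (1389 and 1505) and array weights (882 and 907), and over 15 with a 2-fold threshold (396 and 490). The 20-array count was 987 with the replicate number as a block and 1227 with the 3' minus 5' difference as a covariate. The beta-actin 3' minus 5' difference changed by -1.74 (exact permutation p = 0.00619, 0.0296 after adjustment). With the oligodendrocyte mean as a covariate limma called 0 genes over 15 arrays, with 770 at an unadjusted p under 0.05. The sets, which have arrays in common, shared 967 genes, and 110 of the genes called over 20 arrays had the opposite sign over 15. The 20-array count of 3517 moved with single arrays. It was 2110, 2155, 1981, 1952 and 1867 without P3 replicates 1 to 5 in turn, and 2333 without P8 replicate 5.

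Between P8 and P21 the fast-neuron genes Kcnc1 and Scn4b rose further, Gap43 fell, and Ndufs4 and Stard4 rose, in both sets of arrays. Kcnc1 rose by 2.12 ± 0.30 over 20 arrays and 1.67 ± 0.22 over 15 (adjusted p = 1.01e-04 and 1.23e-04), and Scn4b by 2.86 ± 0.43 and 1.78 ± 0.27 (adjusted p = 2.00e-04 and 4.02e-04). Gap43 changed by -2.62 ± 0.32 and -2.75 ± 0.34 (adjusted p = 3.18e-05 and 9.12e-05), where from P3 to P8 it stood at -0.14 ± 0.30 (adjusted p = 0.739). The respiratory chain gene Ndufs4 rose by 1.31 ± 0.29 and 0.85 ± 0.21 (adjusted p = 0.00421 and 0.00905), and the sterol carrier Stard4 by 1.55 ± 0.32 and 2.19 ± 0.27 (adjusted p = 0.00256 and 7.78e-05).

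The rises over 20 arrays were 5.64 ± 0.64 for Fgf1, 5.01 ± 0.47 for Dao, 4.67 ± 0.83 for Pvalb and 4.39 ± 0.77 for Ermn. The transcription factor Zbtb7a and the lipid enzyme Cds1 rose by 4.20 ± 0.98 and 4.17 ± 0.98 (adjusted p = 0.00644 and 0.00683). Over 15 arrays Fgf1, Dao and Pvalb rose by 6.34 ± 0.77, 5.23 ± 0.58 and 3.45 ± 0.95, a Pvalb call that ended in 2 leave-one-out fits (adjusted p = 0.0641 without P8 replicate 2). Cox8b, Cd24, the homeobox factor Six4 and the inositol transporter Slc5a11 rose by 4.40 ± 0.64, 4.11 ± 0.37, 3.97 ± 1.06 and 3.95 ± 0.58 over 15 arrays. Falls over 20 arrays were -4.62 ± 0.61 for the replication factor Pclaf, -4.26 ± 0.61 for the zinc finger protein Plagl1 and -4.24 ± 0.61 for Gbx2. The calcium-binding protein Rcn1, the actin nucleator Cobl and Ccdc68 changed by -3.57 ± 0.42, -3.31 ± 0.57 and -3.29 ± 0.50 (adjusted p = 2.78e-05, 7.63e-04 and 2.22e-04). Over 15 arrays Scn3a, the synaptic organiser Cbln2, Marchf1 and the retinoic acid binding protein Crabp1 changed by -5.03 ± 0.38, -4.75 ± 0.69, -4.55 ± 0.88 and -3.82 ± 0.51. Glra2 fell by 5.02 ± 0.83 over 15 arrays (adjusted p = 7.65e-04) and stood at -2.17 ± 1.18 over 20 (adjusted p = 0.168).

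Of the 36 lists, 14 were called over 20 arrays and 11 over 15. With an estimated correlation 0 of the former and 3 of the latter held. Over 20 arrays camera with that correlation gave 8 lists at an unadjusted p under 0.05 and fry called 22. Oxidative phosphorylation, cholesterol, bushy cell, cytoskeletal and oligodendrocyte lists were called upwards in both sets. Of 68 oxidative phosphorylation genes, 37 rose, 0 fell and 31 did not pass over 20 arrays, or 47 and 1 adjusted over the list alone. The median was 1.09 (adjusted p = 2.32e-10, and adjusted p = 0.325 with an estimated correlation). Over 15 arrays 12 of 68 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.21 and adjusted p = 8.99e-04, and adjusted p = 0.659 with an estimated correlation. Of 20 cholesterol synthesis genes, 10 rose, 0 fell and 10 did not pass over 20 arrays, or 13 and 0 adjusted over the list alone. The median was 1.35 (adjusted p = 3.64e-06, and adjusted p = 0.137 with an estimated correlation). Over 15 arrays 9 of 20 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.56 and adjusted p = 6.99e-04, and adjusted p = 0.235 with an estimated correlation. Of 24 bushy cell genes, 12 rose, 0 fell and 12 did not pass over 20 arrays, or 14 and 0 adjusted over the list alone. The median was 1.23 (adjusted p = 4.60e-07, and adjusted p = 0.0933 with an estimated correlation). Over 15 arrays 12 of 23 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.98 and adjusted p = 1.11e-04, and adjusted p = 0.235 with an estimated correlation. Of 30 neurofilament and axonal cytoskeleton genes, 10 rose, 1 fell and 19 did not pass over 20 arrays, or 16 and 2 adjusted over the list alone. The median was 0.94 (adjusted p = 0.00232, and adjusted p = 0.146 with an estimated correlation). Over 15 arrays 4 of 29 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.28 and adjusted p = 0.0130, and adjusted p = 0.362 with an estimated correlation. Map1a rose by 0.97 ± 0.22 over 20 arrays (adjusted p = 0.00524). Of 28 oligodendrocyte and myelin genes, 10 rose, 1 fell and 17 did not pass over 20 arrays, or 11 and 1 adjusted over the list alone. The median was 0.67 (adjusted p = 8.77e-04, and adjusted p = 0.221 with an estimated correlation). Over 15 arrays 9 of 27 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.50 and adjusted p = 0.0219, and adjusted p = 0.585 with an estimated correlation. That 15-array call ended in 3 leave-one-out fits (adjusted p = 0.125 without P8 replicate 1). Plekhb1 of this list rose by 2.00 ± 0.33 over 20 arrays (adjusted p = 4.57e-04).

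Axon growth, guidance, cell cycle and oligodendrocyte precursor genes were called downwards in both sets. Of 32 axon growth genes, 2 rose, 14 fell and 16 did not pass over 20 arrays, or 3 and 16 adjusted over the list alone. The median was -0.74 (adjusted p = 0.00223, and adjusted p = 0.169 with an estimated correlation). Over 15 arrays 1 of 31 rose and 18 fell (2 and 20 adjusted over the list alone), with a median of -0.86 and adjusted p = 2.57e-11. Cd24 was again among the members that rose, by 4.02 ± 0.37 over 20 arrays (adjusted p = 3.56e-06). Of 41 axon guidance genes, 0 rose, 13 fell and 28 did not pass over 20 arrays, or 0 and 16 adjusted over the list alone. The median was -0.65 (adjusted p = 0.00233, and adjusted p = 0.0521 with an estimated correlation). Over 15 arrays 2 of 40 rose and 13 fell (2 and 15 adjusted over the list alone), with a median of -0.51 and adjusted p = 3.30e-05. Efnb3 and the semaphorin receptor Plxna1 changed by -3.17 ± 0.39 and -1.43 ± 0.28 over 20 arrays (adjusted p = 3.18e-05 and 0.00203). Of 33 cell cycle genes, 2 rose, 16 fell and 15 did not pass over 20 arrays, or 2 and 20 adjusted over the list alone. The median was -0.97 (adjusted p = 2.21e-04, and adjusted p = 0.137 with an estimated correlation). Over 15 arrays 1 of 32 rose and 12 fell (1 and 12 adjusted over the list alone), with a median of -0.51 and adjusted p = 6.99e-04, and adjusted p = 0.140 with an estimated correlation. Ccnb2 changed by -2.81 ± 0.46 and Ccnd1 rose by 1.98 ± 0.33 over 20 arrays (adjusted p = 4.31e-04 and 5.20e-04). Of 11 precursor markers, 0 rose, 5 fell and 6 did not pass over 20 arrays, or 0 and 5 adjusted over the list alone. The median was -0.84 (adjusted p = 0.00506, and adjusted p = 0.0933 with an estimated correlation). Over 15 arrays 0 of 10 rose and 5 fell (1 and 6 adjusted over the list alone), with a median of -0.95 and adjusted p = 0.00168. Cspg5 and Pdgfra changed by -3.01 ± 0.45 and -2.05 ± 0.39 over 20 arrays (adjusted p = 1.85e-04 and 0.00143).

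Further lists were called in 1 set of arrays. Over 20 arrays, upwards, in the tricarboxylic acid cycle 12 of 19 rose and 0 fell, or 17 and 0 adjusted over the list alone. The median was 1.47 (adjusted p = 3.64e-06, and adjusted p = 0.344 with an estimated correlation). Sdha, of both the cycle and the respiratory chain, rose by 1.33 ± 0.29 (adjusted p = 0.00423). In glycolysis, also upwards, 10 of 27 rose and 2 fell, or 16 and 3 adjusted over the list alone. The median was 1.17 (adjusted p = 4.80e-04, and adjusted p = 0.344 with an estimated correlation). Of endocytosis genes, upwards, 10 of 36 rose and 3 fell, or 10 and 3 adjusted over the list alone. The median was 0.59 (adjusted p = 0.0271, and adjusted p = 0.344 with an estimated correlation). Downwards over 20 arrays, of axon injury genes 1 of 21 rose and 6 fell, or 1 and 8 adjusted over the list alone. The median was -0.60 (adjusted p = 0.00955, and adjusted p = 0.350 with an estimated correlation). The tubulin Tubb2b changed by -2.65 ± 0.42 (adjusted p = 3.37e-04). Of inhibitory neuron markers, downwards, 0 of 12 rose and 1 fell, or 0 and 0 adjusted over the list alone. The median was -0.94 (adjusted p = 0.0190, and adjusted p = 0.269 with an estimated correlation). The member that fell was the homeobox factor Dlx1, with -1.47 ± 0.47 (adjusted p = 0.0348), a call that ended in 6 leave-one-out fits (adjusted p = 0.110 without P21 replicate 2). Over 15 arrays, downwards, of ribosomal proteins 0 of 41 rose and 19 fell, or 0 and 25 adjusted over the list alone. The median was -0.44 (adjusted p = 4.99e-10, and adjusted p = 0.269 with an estimated correlation). Over 20 arrays their median was 0.092 while the test pointed down (adjusted p = 0.900). Of neuronal adhesion molecules, downwards over 15 arrays, 0 of 38 rose and 10 fell, or 1 and 12 adjusted over the list alone. The median was -0.30 (adjusted p = 0.00374, and adjusted p = 0.235 with an estimated correlation). The adhesion molecule Chl1 changed by -1.74 ± 0.27 (adjusted p = 4.10e-04).

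Calb2 rose by 2.74 ± 0.52 and Slc17a7 by 1.35 ± 0.44 over 20 arrays (adjusted p = 0.00150 and 0.0368). Mbp rose by 1.81 ± 0.61 over 20 arrays but stood at 0.25 ± 0.37 over 15 (adjusted p = 0.0398 and 0.674). Over 20 arrays the Slc17a7 and Mbp calls ended in 5 and 10 leave-one-out fits (adjusted p = 0.0844 and 0.0831 without P21 replicate 3). In all, 1354 genes were higher and 1372 lower at P21 than at P8 over 20 arrays, and 1141 and 1175 over 15. With array medians subtracted 1599 and 1177 were higher and lower over 20 arrays, and with a filter at log2 6 1441 and 1061. The 20-array count was 943 with the replicate block, 1031 with the 3' minus 5' covariate and 218 with the oligodendrocyte covariate. The sets shared 1218 genes. The GAPDH 3' minus 5' difference was 1.31 higher at P21 than at P8 (exact permutation p = 0.00450, 0.0296 after adjustment), and 0.72 higher than in P8 replicates 1 to 4 (exact permutation p = 0.111, 0.194 after adjustment). The 20-array count of 2726 was 4310 without P8 replicate 3, and 1596, 1442, 1375, 1652 and 1693 without P21 replicates 1 to 5 in turn.

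The last comparison asks whether genes moved by different amounts before and after P8. Scn4b and Kcnc1 rose in both intervals. For Gap43 the second change minus the first was -2.48 ± 0.51 over 20 arrays and -2.74 ± 0.60 over 15 (adjusted p = 0.00548 and 0.0174). For Fgf1 this difference was 6.02 ± 1.03 over 20 arrays and 7.42 ± 1.34 over 15 (adjusted p = 0.00237 and 0.00712), and for Dao 3.99 ± 0.75 over 20 arrays and 4.43 ± 1.02 over 15 (adjusted p = 0.00395 and 0.0216). For Dcx it was 3.64 ± 0.93 over 20 arrays and 0.76 ± 0.39 over 15 (adjusted p = 0.0131 and 0.261). Cd24, which fell before P8 and rose after it, gave 6.68 ± 0.59 over 20 arrays and 6.86 ± 0.65 over 15 (adjusted p = 2.86e-06 and 1.57e-04). The myelin gene Mobp gave -2.63 ± 0.85 over 20 arrays and -3.65 ± 0.88 over 15 (adjusted p = 0.0273 and 0.0265).

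By the moderated F test 5182 of 12705 genes differed among the ages over 20 arrays and 5198 of 11830 over 15. With the replicate block and the 3' minus 5' covariate the 20-array count was 2543 and 2648, and with the oligodendrocyte covariate the 15-array count was 1037. Over 20 arrays 899 genes were called in both intervals, 176 in the same direction and 723 in opposite directions. That balance turned with array weights (186 and 145), the replicate block (91 and 63), the 3' minus 5' covariate (102 and 86) and the oligodendrocyte covariate (38 and 6). Over 15 arrays 586 were called in both, 357 in the same direction and 229 in opposite ones. Over 20 arrays independent lists would give 215 up in both, 161 down in both, 218 up then down and 159 down then up, where 87, 89, 440 and 283 were observed. Over 15 arrays they would give 106, 94.2, 109 and 91.4, where 226, 131, 122 and 107 were observed. Both intervals share the P8 arrays, whose chance values push the changes apart. The correlation across genes was -0.536 over 20 arrays and -0.0589 over 15 (simulated -0.377 and -0.579). The covariances were -0.515 and -0.0284 (simulated -0.0704 and -0.0553). No gap between P8 sets was simulated. With P8 replicates 1 to 4 split into 2 and 2, each pair serving 1 interval, the mean correlation over 6 splits was 0.127 and the mean covariance 0.0732. Genes are not independent replicates, so these correlations carry no p.

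The interval difference itself passed for 4190 genes over 20 arrays and 627 over 15. With array weights these counts became 161 and 295, with the replicate block 139 and 173, with the 3' minus 5' covariate 347 and 690, and with the oligodendrocyte covariate 5795 and 29. The count called in both intervals over 20 arrays moved with every array left out. It was 1825 to 2119 without 1 of P8 replicates 1 to 4, and 375 to 558 without 1 of the other 16 arrays, lowest without P21 replicate 3. The count for the interval difference was 2531, 2590, 2774 and 2647 without P8 replicates 5 to 8 in turn over 20 arrays. Over 15 it was 306, 269 and 1046 without P8 replicates 2 to 4 in turn.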

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

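The tests of P8 replicates 5 to 9 were chosen only after their result was seen, as were the splits over 15 arrays, and the splits over 20 arrays were planned. For each comparison 100 splits of its arrays into groups of the same sizes were drawn, the real one included. Over 20 arrays P8 vs P3 called 3517 genes and the highest other split 2486, and P21 vs P3 1931 against 0 by limma, so for both chance can be excluded (1 split as large in each). For P8 vs P3 this does not separate age from raised spike-in controls. All 5 such arrays were at P8, and the highest other split put 4 into its group of 6. For P21 vs P8 over 20 arrays 5 of the splits were as large as the real one, with 2726 real and 5469 highest, so chance cannot be excluded there. The highest count points to a structure of the samples, since its split put 4 of those 5 arrays into its group of 5. Within the 15 arrays P21 vs P8 called 2316 genes and the highest other split 807, and chance can be excluded (1 split as large). Over 15 arrays the same holds for P8 vs P3, with 2046 against 7 (1 split as large), and for P21 vs P3, with 5074 against 3446 (1 split as large).

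Single arrays lay far from the others of their age in 23 of 408 groups of values, where chance gives about 1 in 20. Values are log2 levels or log2 differences unless named otherwise. Cacna1a was 5.33 in P3 replicate 6, above the next at 4.74, Cplx2 was 3.22 in P8 replicate 4, below the next at 5.00 and Gabrd was 6.69 in P21 replicate 4, below the next at 7.78. Gad1 was 10.003 in P3 replicate 2, above the next at 9.44, Marchf1 was 3.91 in P8 replicate 9, below the next at 6.70 and Mbp was 10.77 in P21 replicate 5, below the next at 11.32. Myh6 was 5.17 in P3 replicate 3, below the next at 6.88, Nefh was 10.83 in P21 replicate 5, below the next at 11.46 and Rims1 was 5.64 in P21 replicate 5, above the next at 4.80. Scn4b was 10.91 in P21 replicate 5, below the next at 11.47, Unc13b was 3.62 in P21 replicate 1, above the next at 2.41 and Pclaf was 2.14 in P21 replicate 1, below the next at 4.25. Sdha was 10.10 in P21 replicate 2, above the next at 9.92, Six4 was 7.70 in P21 replicate 4, below the next at 9.10 and C1qtnf12 was 6.13 in P21 replicate 5, above the next at 5.37. Cd14 was 3.10 in P21 replicate 1, below the next at 4.50, Ctss was 7.74 in P21 replicate 4, below the next at 8.53 and Mcm7 was 4.73 in P8 replicate 8, below the next at 6.28. Myc was 7.81 in P3 replicate 5, above the next at 7.17, Rps15a was 9.57 in P3 replicate 1, below the next at 10.17 and the beta-actin 3' minus 5' difference was 5.51 in P21 replicate 1, above the next at 4.26. The mean correlation with the own age was 0.935 in P3 replicate 1, below the next at 0.948 and the mean of markers of microglia and macrophages was 4.61 in P3 replicate 1, below the next at 5.16.

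P8 replicates 5 to 9 had raised spike-in controls, higher medians and other patterns than the rest of the arrays. Random loss of signal from less labelled RNA is argued against. Over bright probe sets these arrays shared deviations from P8 replicates 1 to 4, each from other reference arrays. The median pairwise correlation was 0.688 (lowest pair 0.597, highest 0.763). Raised spike-in controls on scaled arrays leave open less labelled RNA with shared loss, as by sequence, which was not tested. RNA of another cell type in the material dissected by laser from labelled cells stays open: 0 of 11 marker lists lay above the bound set from random lists, but cerebellar granule cell markers reached percentile 98.99 with a median rise of 1.13. Repeat-containing sequence, from unspliced RNA or genomic DNA, may also be a source and stays open, as the repeat controls rose by 0.28 more than the spike-in controls on average (-0.48 to 0.83 per array), B1 by 1.25 to 1.84 and B2 by -2.56 to 0.058. The design gives no group within P8, so no biological explanation was tested.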

How the results depend on the processing

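Leaving out P8 replicates 5 to 9 with every setting over 15 arrays, and the pseudocount of 16, were chosen after seeing the data, and the other settings were planned. For the values below that differ from those of the report the cause was not tested. Other filters, quantile normalization, subtracted medians, a floor, eBayes with trend, other uses of probe sets and a pseudocount of 16 kept each count of genes within 1.5 times of the reported count. Few arrays per age limit all counts. Signal near background limits what can be said of dim genes, whose changes the pseudocount shrinks and whose absence is not shown by a low value. With array weights over 20 arrays the counts were 1789 for P8 vs P3, 1649 for P21 vs P8, 5794 for P21 vs P3, 331 for both intervals and 161 for the interval difference. With array weights over 15 arrays the count was 295 for the interval difference. With the oligodendrocyte covariate over 20 arrays the counts were 218 for P21 vs P8, 4 for P21 vs P3 and 44 for both intervals, and 5 lists for P8 vs P3. With the oligodendrocyte covariate over 15 arrays the counts were 0 for P8 vs P3 (770 at unadjusted p < 0.05, 2046 without it), 1401 for P21 vs P8, 18 for P21 vs P3, 1037 for any age, 0 for both intervals (358 at unadjusted p < 0.05, 586 without it) and 29 for the interval difference, and 2 lists for P8 vs P3 and 6 lists for P21 vs P3. With the 3' minus 5' covariate over 20 arrays the counts were 1227 for P8 vs P3, 1031 for P21 vs P8, 2648 for any age, 188 for both intervals and 347 for the interval difference. By the exact Mann-Whitney test over 20 arrays the counts were 2017 for P8 vs P3, 1359 for P21 vs P8, 5146 for P21 vs P3 and 262 for both intervals. By the exact Mann-Whitney test over 15 arrays the counts were 0 for P8 vs P3 (3124 at unadjusted p < 0.05, 2046 by limma), 0 for P21 vs P8 (2577 at unadjusted p < 0.05, 2316 by limma) and 0 for both intervals (886 at unadjusted p < 0.05, 586 by limma). With only the 2 ages compared over 20 arrays the counts were 1465 for P8 vs P3, 905 for P21 vs P8 and 5732 for P21 vs P3. With only the 2 ages compared over 15 arrays the count was 1341 for P21 vs P8. With an estimated correlation over 20 arrays the counts were 0 lists for P8 vs P3 (4 at unadjusted p < 0.05, 8 by camera at the preset), 0 lists for P21 vs P8 (8 at unadjusted p < 0.05, 14 by camera at the preset) and 5 lists for P21 vs P3. With an estimated correlation over 15 arrays the counts were 1 list for P8 vs P3, 3 lists for P21 vs P8 and 1 list for P21 vs P3. By fry over 20 arrays the counts were 22 lists for P21 vs P8 and 15 lists for P21 vs P3. By fry over 15 arrays the count was 27 lists for P21 vs P3. Without P8 replicates 5 to 9 the counts were 2046 for P8 vs P3, 5074 for P21 vs P3, 586 for both intervals and 627 for the interval difference, and 13 lists for P8 vs P3. With a 2-fold threshold added over 15 arrays the counts were 886 for P8 vs P3, 1152 for P21 vs P8, 2414 for P21 vs P3, 2814 for any age and 196 for both intervals. The oligodendrocyte mean follows age, so that covariate can take up change with age, but over 20 arrays it left 3178 genes for P8 vs P3, 4968 for any age and 5795 for the interval difference.

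The labels do not say that equal replicate numbers pair the arrays. Deviations from the age means of the 13 pairs with the same number correlated at 0.0112 on average over 15 arrays, none above 0.1, and 6 of the 15 arrays had their best partner at the same number, with 2.63 expected from random partners. With the replicate block over 20 arrays the counts were 987 for P8 vs P3, 943 for P21 vs P8, 2543 for any age, 154 for both intervals and 139 for the interval difference. With the replicate block over 15 arrays the counts were 1167 for P8 vs P3, 309 for both intervals and 173 for the interval difference. With the replicate block, over 20 arrays, turned values were Gap43 0.024, microglia and macrophages -0.086, synaptic vesicle proteins 0.11 (P8 vs P3) and cytosolic ribosomal proteins -0.23, called at adjusted p = 0.0237 (P21 vs P8). With the replicate block, over 15 arrays, the sign turned for Gap43 0.15 (P8 vs P3).

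Changes of named genes and list means that turned sign follow, on the log2 scale. With no filter, over 20 arrays, the sign turned for synaptic vesicle proteins 0.052 (P8 vs P3). With array medians subtracted, over 20 arrays, turned values were Slc12a5 -0.011 and calcium buffers, pumps and exchangers -0.055 (P8 vs P3). With array medians subtracted, over 15 arrays, the sign turned for Gap43 0.0097 (P8 vs P3). With the mean of probe sets, over 20 arrays, turned values were Bsn 0.14 and Pclo -0.47 (P21 vs P3). With the mean of probe sets, over 15 arrays, the sign turned for Pclo -0.47 (P21 vs P3). With the oligodendrocyte covariate, over 20 arrays, turned values were Bsn 0.029, Calb2 -0.36, Ccnb2 0.30, Cplx1 -0.69, Cplx2 3.44 and Ermn -1.25 (P21 vs P3). Further ones were Fdft1 -0.25, Mbp -2.44, Myh6 2.46, Nefh -0.43, Nefm -1.78 and Slc12a5 -0.95 (P21 vs P3). Others were Slc17a6 -1.26, Tprg1l -1.98, Unc13b 2.98, Vamp1 -2.20 (P21 vs P3), Mbp -0.28 (P21 vs P8) and Calb1 -1.41 (P8 vs P3). Others were Calb2 -1.87, Cntnap1 -0.70, Ctss 0.40, Eri2 0.28, Gap43 0.081 and Htr2c -0.10 (P8 vs P3). Others were Kcna1 -1.39, Mbp -2.16, Slc12a5 -1.10, Slc24a2 -1.11, Syn2 -0.93 and Vamp1 -2.52 (P8 vs P3). Others were calcium buffers, pumps and exchangers -0.69, cell cycle 0.073, cerebellar granule cells 0.76, oligodendrocytes and myelin 0 by construction (P8 vs P3), cytosolic ribosomal proteins -0.43, called at adjusted p = 8.52e-04 (P21 vs P8) and BMP and TGF-beta signalling 0.38 (P21 vs P3). Others were GABA and glycine receptors and chloride transporters -0.66, astrocytes -0.98, cerebellar granule cells 1.33, cholesterol synthesis -0.94, glycolysis and lactate metabolism -1.51, called at adjusted p = 0.0164 and neurofilaments and mature axonal cytoskeleton -0.31 (P21 vs P3). Others were oxidative phosphorylation -0.91, called at adjusted p = 0.0434, synaptic vesicle proteins -0.80 and tricarboxylic acid cycle -2.08, called at adjusted p = 0.00184 (P21 vs P3). With the oligodendrocyte covariate, over 15 arrays, turned values were Bsn 0.81, Cplx2 2.86, Mbp -0.18, Myh6 0.016, Pclo -0.20 and Syt1 -0.34 (P21 vs P3). Further ones were Tprg1l -0.18 (P21 vs P3), Mbp -0.66 (P21 vs P8), Col9a3 -0.29, Enpp6 -0.91, Gap43 0.092 and Pnlip -0.017 (P8 vs P3). Others were choroid plexus and ependyma -0.024 (P8 vs P3), BMP and TGF-beta signalling 0.11, GABA and glycine receptors and chloride transporters -0.079, astrocytes -0.32, cerebellar granule cells 0.33 and fibroblasts and meninges -0.14 (P21 vs P3). Others were synaptic vesicle proteins -0.095 (P21 vs P3). With a pseudocount of 16, over 20 arrays, turned values were calcium buffers, pumps and exchangers -0.0068 (P8 vs P3) and astrocytes -0.027 (P21 vs P3). With a pseudocount of 16, over 15 arrays, the sign turned for astrocytes -0.028 (P21 vs P3). Without P8 replicates 5 to 9, turned values were Dlst 0.87, called at adjusted p = 0.00269, endocytosis and vesicle recycling 0.19, called at adjusted p = 0.0376, microglia and macrophages -0.68, called at adjusted p = 0.00625, oxidative phosphorylation 0.28, called at adjusted p = 1.11e-04, synaptic vesicle proteins 0.33, called at adjusted p = 1.13e-04 and tricarboxylic acid cycle 0.23, called at adjusted p = 0.0484 (P8 vs P3). It also turned for cytosolic ribosomal proteins -0.52, called at adjusted p = 4.99e-10 (P21 vs P8).

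With each array left out in turn, counts over 20 arrays ranged over 1867 to 4951 for P8 vs P3, 1375 to 4310 for P21 vs P8, 375 to 2119 for both intervals and 2531 to 5568 for the interval difference. Over 15 arrays they ranged over 269 to 1046 for the interval difference. The log2 changes whose side of the threshold or sign moved in any such fit ranged as follows over 20 arrays. Bsn -0.18 to 0.055, Cacna1b -1.11 to -0.92, Cd24 1.24 to 1.51, Glra2 -5.17 to -3.98, Nefh 1.29 to 1.50, Slc12a5 0.90 to 1.10 and Slc17a7 1.17 to 1.55 (P21 vs P3). Syt2 0.96 to 1.42, Vamp1 2.35 to 2.62 and astrocytes -0.035 to 0.10 (P21 vs P3). Calb1 1.62 to 2.26, Calb2 -0.052 to 0.43, Cd14 -2.39 to -1.74, Cntnap1 1.68 to 2.23, Mbp 1.13 to 1.65, Mcm7 -1.11 to -0.76 and Ndufs4 0.82 to 1.10 (P8 vs P3). Slc12a5 -0.021 to 0.23, Snap25 0.68 to 0.92, bushy cell and fast auditory neuron genes 0.51 to 0.72, calcium buffers, pumps and exchangers -0.0089 to 0.14, oxidative phosphorylation -0.54 to -0.31, synaptic vesicle proteins -0.060 to 0.050 and voltage-gated potassium and HCN channels 0.44 to 0.50 (P8 vs P3). Cbln2 -3.79 to -2.70, Dlx1 -1.86 to -1.16, Mbp 1.58 to 2.04, Slc17a7 1.11 to 1.49, cell adhesion molecules of neurons -0.48 to -0.38 and cytosolic ribosomal proteins -0.044 to 0.13 (P21 vs P8). Over 15 arrays they ranged as follows. Bsn -0.18 to 0.055, Nefm 0.21 to 0.40, Pclo 0.32 to 0.54, Slc17a7 1.17 to 1.55, Snap25 0.34 to 0.54, Syt2 0.96 to 1.42 and astrocytes -0.042 to 0.10 (P21 vs P3). Glycolysis and lactate metabolism 0.30 to 0.40, neurofilaments and mature axonal cytoskeleton 0.31 to 0.39 and synaptic vesicle proteins 0.092 to 0.15 (P21 vs P3). Ctss -1.66 to -1.16, Eri2 -3.84 to -1.99, Gap43 -0.15 to 0.15, Myc -1.38 to -1.12, Syt2 0.78 to 1.56, cerebellar granule cells -0.81 to -0.67 and endocytosis and vesicle recycling 0.15 to 0.21 (P8 vs P3). Tricarboxylic acid cycle 0.17 to 0.32 (P8 vs P3). Pvalb 2.63 to 4.30, Slc17a7 1.49 to 2.50 and oligodendrocytes and myelin 0.50 to 0.67 (P21 vs P8). Over all settings 4079 of the gene values over 20 arrays and 3183 over 15 kept direction and side of the threshold, 196 and 151 lost the call, 32 and 6 gained it and 39 and 20 turned.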

Other observations

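The tests of the oligodendrocyte genes and of the inflammatory genes were chosen only after their result was seen. Several lists not called between P3 and P21 over 20 arrays held members that moved in opposite directions. In the sodium channel list 5 of 15 genes rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.894). Scn4b rose, while Scn3b, Scn3a and Scn2a, channels of immature neurons, changed by -3.17 ± 0.34, -5.79 ± 0.67 and -2.41 ± 0.36 (adjusted p = 2.44e-06, 4.84e-06 and 6.93e-05). In the list of GABA and glycine receptors and chloride transporters 3 of 19 genes rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.429). The adult glycine receptor subunit Glra1 rose by 2.96 ± 0.67 and the immature Glra2 fell by 4.57 ± 1.28 (adjusted p = 0.00380 and 0.0177). Gabra6 and Gabrd, subunits abundant in cerebellar granule cells, rose by 4.48 ± 0.71 and 2.39 ± 0.44 (adjusted p = 1.61e-04 and 6.01e-04), while of granule cell markers 2 of 13 genes rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.403), with a median of -0.40. Among ionotropic glutamate receptors and their partners 2 of 28 genes rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.894). The receptor subunit Grin2c rose by 2.59 ± 0.28 and the AMPA receptor partner Cnih2 fell by 3.29 ± 0.32 (adjusted p = 2.86e-06 and 7.89e-07). That list's median was 0.22 with a mean of -0.044.

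For BMP and TGF-beta signalling 4 of 40 genes rose and 6 fell (4 and 8 adjusted over the list alone; adjusted p = 0.403). The activin and inhibin subunits Inhbb and Inhba rose by 4.53 ± 0.51 and 3.60 ± 0.49 (adjusted p = 3.95e-06 and 3.29e-05). Of astrocyte markers 1 of 25 genes rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.722), and their median of -0.037 and mean of 0.053 differed in sign. The astrocyte connexin Gjb6 rose by 5.03 ± 0.47 and the glutamate transporter Slc1a3 fell by 2.08 ± 0.27 (adjusted p = 6.17e-07 and 1.62e-05). The list of fibroblasts and meninges also differed in sign, with a median of -0.025 and a mean of 0.18.

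The rise of oligodendrocyte and myelin genes from P3 to P21 has RNA of neighbouring oligodendrocytes as a candidate source. Within ages, over the 15 arrays, the list's genes deviated together, with a mean pairwise correlation of 0.199. Random lists had a median of 0.00762 and a 99th percentile of 0.0785. Bushy cell (0.184) and ribosomal (0.360) lists also passed that percentile and others did not, so this leaves the source open. Of the 28 genes 3 are also in another list, and the abundant Mbp and Mobp averaged 11.27 and 10.22 at P21 and 8.10 and 5.13 at P3. Laser microdissection of labelled cells was the step that should remove such RNA. Myelination with age in the surrounding tissue stays open as well and was not tested.

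A list of 58 NF-kB and interferon response genes, compiled after the falls of such genes had been seen and so not independent evidence, fell from P3 to P8 over 15 arrays in 19 of 44 tested genes with 0 rising by limma (median -1.42), and from P3 to P21 in 21 (median -1.36). Its mean was 6.21, 7.03, 4.21, 4.28, 5.99, 5.89 in P3 replicates 1 to 6, 3.55 to 4.13 in P8 replicates 1 to 4, 5.17 to 5.61 in P8 replicates 5 to 9 and 3.90 to 4.14 at P21. More endothelial RNA at P3 is argued against, as the change of the 21 endothelial genes from P3 to P8 was -0.145 of that of the list (95% bootstrap interval over its genes -0.312 to 0.196). More microglial RNA at P3 may be a source and stays open, with 0.484 (0.129 to 0.734; 17 genes, none of them in another list) in material that laser microdissection of labelled cells should have kept apart. The microglial marker mean was 4.61, 5.20, 5.17, 5.33, 5.16, 5.31 in P3 replicates 1 to 6, in another order than the list's mean, and 4.53 ± 0.43 in P8 replicates 1 to 4. Age and the response to the injection made 24 hours before stay open as well and were not tested.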
